A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

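Budding yeast (Saccharomyces cerevisiae, strain background W303) of 4 genotypes was profiled: wild type, an msp1 deletion, a pex19 deletion and a deletion of both genes. Each genotype had 1 RNA-seq library and 1 library of ribosome-protected fragments (RPF), 8 libraries in all. Per the labels' protocols, cells grew in synthetic complete medium with 2% glycerol and 2% ethanol as carbon source. A final culture of 500 mL was started at an optical density of 0.1 and harvested 16 h later at a density between 2 and 2.5, by vacuum filtration and flash freezing. Ribosomes were arrested in the lysate with cycloheximide and tigecycline, and RNase I-treated monosomes were purified over a 10 to 50% sucrose gradient, per the labels' protocols. RNA-seq libraries came from 5 µg of total RNA depleted of ribosomal RNA, with fragments of 19 to 40 nt, and RPF fragments measured 19 to 33 nt. Reads were 60 nt, single-end, from an Illumina sequencer, per the labels' protocols. Spike oligonucleotides (2 fmol of each per sample) were added per the same protocols. No entry of the gene tables is named for them, so they are not used here and all values are relative within an assay.

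Per the submitters' processing notes, cutadapt 1.8 and STAR 2.5 and the genome build sacCer3 (R64) were used; the tool that counted reads per gene is not given in the sources used here. Every file lists the same 6668 genes. The authors' deposited read counts, headed as reads in the file headers, are whole numbers and were the input of every calculation. The lowest count listed is 1, never 0, and the deleted genes are listed at 1 in their deletion strains, so a gene without reads appears as 1; whether 1 was added to every count or only to empty genes is not given in the sources used here. The deposited TPM values, per the file headers, are the authors' length-scaled values; they were not used for tests. The file of the double deletion's RNA-seq library alone also holds RPM and RPKM columns, per the file headers. The authors' deposited RPM and RPKM imply, for 5716 of 5994 genes with a reference coding length, a length 50 nt shorter than the coding sequence; these columns were used only for that check. The files of the double deletion ended in 2 blank lines each, which were dropped. Mitochondrially encoded genes are not analysed here. Gene positions, coding lengths and sequences come from the R64 reference, in which 5994 of the listed genes were found.

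Library totals were 5367091 reads (wild type), 5302691 (msp1), 4694951 (pex19) and 4936802 (double) for RNA-seq. For RPF they were 2133432, 1101458, 2300792 and 1685722 in the same order. Counts were scaled within each assay by TMM (edgeR 4.0.16, R 4.3.3). The factors were computed on genes with a mean of at least 50 counts in the assay. This restriction was chosen after the files were seen, because the listed minimum of 1 distorts ratios of low genes; TMM over all listed genes is given as an alternative. A log2 ratio used a pseudocount of 1 read, scaled to library size. Genes were kept with a mean of at least 50 counts over the 4 libraries in each assay, which left 3737. Translational efficiency is the RPF ratio divided by the RNA-seq ratio. The nonadditive value is the double deletion's log2 value minus those of both single deletions plus that of wild type.

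With 1 library per genotype and assay there is no spread between replicates, so no test was run and no p-value is given. Each ratio has an exact (Clopper-Pearson, conditional binomial) 95% interval. PCR reads without molecular identifiers are not independent molecules, so these intervals, and the limit of 3 reads used for an unread gene, cover counting error only. Genes at least 2-fold higher, or lower, in both the RNA-seq and the RPF library were counted. By the series' design text the 2 libraries of a genotype belong to 1 sample, so agreement between them bears on library noise and not on variation between cultures. For the 37 of 38 gene lists with a measured member, the median log2 ratio of the measured members was placed among 10000 random lists matched on deciles of mean count. That percentile describes these libraries and is not a p-value; the interval of a list median is a bootstrap over its genes.

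The genes named follow a fixed rule. It takes MSP1 and PEX19 with the annotated neighbours on each side; for each deletion against wild type, up to 10 genes per direction past 2-fold in both assays; up to 5 per direction by translational efficiency; up to 4 members per described list; all members of lists of at most 10 genes; and the 5 highest and lowest nonadditive genes and those of the double deletion against each single one. Near-identical copies of named genes were sought by blastn (at least 90% identity over at least 100 nt of coding sequence); how reads shared by such copies were counted, and whether strand was used, is not given in the sources used here. Lists of zinc genes were set up after zinc genes had been noticed in these ratios. The sample groups, comparisons, all other gene lists, naming rule and most alternative settings were fixed before the data were examined. Those settings were scaling by library total, DESeq2 1.42.0 size factors, other count minimums (200, 10, none), pseudocounts of 5 and 0.1, each assay alone, a 1.5-fold threshold and leaving out ribosomal protein genes. Scaling by the spike oligonucleotides was not run, and there was no replicate to leave out. A cubic trend of the log2 ratio on coding length and GC was removed as a further alternative, chosen after the counts were seen.

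The calculations were checked on simulated counts in which 200 genes were changed. These counts held counting error alone, without variation between libraries, and the 3-fold and 4-fold changes lay well past the 2-fold limit. The figures therefore check the calculations and are not error rates of the real libraries. For msp1 against wild type, all 39 genes changed 3-fold in both assays were recovered (100%), as were 100% of 38 genes changed 4-fold, and 0 of 3540 unchanged genes passed 2-fold in both assays. For pex19 against wild type 100% of 37 genes at 3-fold were recovered, with 0 of 3539 unchanged genes; for the double deletion, 100% of 39 genes at 3-fold, with 0 of 3545. Intervals of unchanged genes held 0 in 95.7%, 95.2% and 96.0% of 1000 genes, respectively. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.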

Results

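RNA-seq and ribosome profiling were compared across wild-type yeast, strains lacking MSP1 or PEX19, and a strain lacking both. MSP1 encodes an AAA ATPase of the outer mitochondrial membrane that extracts mislocalised tail-anchored proteins, and PEX19 encodes the cytosolic import receptor and chaperone for peroxisomal membrane proteins. By its title, the study concerned mitochondrial dysfunction in Zellweger spectrum disorder. Each genotype had 1 RNA-seq and 1 RPF library, so no ratio below has a replicate check. RNA-seq libraries held 4694951 to 5367091 reads on 6668 listed genes. RPF libraries held 1101458 to 2300792, with the lowest total in the msp1 deletion, and 3737 genes passed the count minimum.

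MSP1 and PEX19 reads matched the genotype labels in all 8 libraries. MSP1 (YGR028W; chromosome VII, 542203 to 543291, 1 coding exon) had 731 RNA-seq and 122 RPF reads in wild type, 607 and 175 in the pex19 deletion, and was listed at 1 in the msp1 and double deletions. Its RNA was at least 236-fold lower in the msp1 deletion than in wild type and its RPF at least 21.4-fold lower, taking 3 reads as the limit. PEX19 (YDL065C; chromosome IV, 336249 to 337277, 1 coding exon) had 387 RNA-seq and 216 RPF reads in wild type, 365 and 104 in the msp1 deletion, and 1 in the pex19 and double deletions. Its RNA was at least 109-fold lower and its RPF at least 77.9-fold lower in the pex19 deletion than in wild type.

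A gene adjacent to each deletion also differed. ERV1 (YGR029W; chromosome VII, 543553 to 544205), next to MSP1, encodes a sulfhydryl oxidase of the mitochondrial intermembrane space. Its log2 ratio to wild type was −0.71 in RNA-seq and −1.39 in RPF in the msp1 deletion and −1.0 and −1.90 in the double deletion, with 166 RPF reads in wild type against 33 and 35. UBC9 (YDL064W; chromosome IV, 337487 to 338070), next to PEX19, encodes the SUMO-conjugating enzyme. Its ratio was 1.63 and 0.88 in the pex19 deletion and 1.29 and 0.69 in the double deletion, in RNA-seq and RPF. IDP1 and COX9, on the other side of PEX19, had log2 ratios to wild type between −0.15 and 0.21 in every deletion and both assays. SYO1, POP6 and the Ty elements YGR027W-A and YGR027W-B did not pass the count minimum, and both Ty elements, listed at 1 in every library, have near-identical copies.

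In the msp1 deletion a few genes were higher than in wild type in both assays, which addressed what loss of MSP1 alone does. ZPS1, a cell-surface protein gene expressed at low zinc (YOL154W; chromosome XV, 34658 to 35407), was 1.86 higher in RNA-seq (95% counting interval 1.62 to 2.12) and 3.10 in RPF (2.66 to 3.63), on the log2 scale. HEF3, a translation elongation factor 3 paralogue, was 1.20 and 3.02 higher, with 35 RPF reads in wild type and 154 in the deletion. IMD2, inosine monophosphate dehydrogenase of guanine nucleotide synthesis, was 1.74 and 1.83 higher. MF(ALPHA)1, the α-factor precursor, was 1.21 and 1.57 higher, SSA3, a stress-inducible Hsp70, 1.11 and 1.15, and ADH4, an alcohol dehydrogenase expressed at low zinc, 1.02 and 1.03. These 6 genes were all that were at least 2-fold higher in both libraries, and MSP1 was the only one lower. If the assays were independent and every gene equally likely to pass, 0.15 and 0.025 genes would be shared by chance. MSP1, as the deleted gene, was bound to be shared, and without it 0 genes were lower. ADH4 stood at the limit and dropped out when libraries were scaled by their totals (RNA-seq 0.99), and it and SSA3 dropped out under TMM over all listed genes (RPF 0.83 and 0.95).

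Cytosolic ribosomal protein genes were lower in the msp1 deletion, with 126 of 137 below wild type in RNA-seq (median −0.21) and 135 in RPF (−0.50). RPL35A was −0.46 and −1.20, RPL7B −0.17 and −1.36, and RPL41A 0.36 and 0.62. RPL35A and RPL7B share 99.2% and 96.7% of their coding sequence with RPL35B and RPL7A, so their single values are uncertain. The 15 measured genes of the ER unfolded protein response had medians of 0.23 and 0.39, with the Hsp70 KAR2 at 0.40 and 0.71. These medians stood at percentiles 99.99 and 99.9 of matched random lists. Of 26 general stress genes of Msn2 and Msn4, 22 were higher in RNA-seq (median 0.20) and 17 in RPF (0.16). Glycolytic genes had medians of 0.23 and 0.13 and included PDC1 at 0.41 and 0.42. The RPF medians of the Msn2 and Msn4 and the glycolytic list turned to −0.04 and −0.08 under TMM over all listed genes, a scaling that moved the RPF median of all genes from 0.0147 to −0.185 in this comparison. The 74 mitochondrial ribosomal protein genes had medians of −0.12 in RNA-seq and −0.16 in RPF; the latter became 0.00424 after removal of the length and GC trend. Translation factor genes had medians of −0.08 and −0.26 and ergosterol biosynthesis genes 0.08 and 0.38. Of 35 lists with at least 3 measured genes, 3 lay in the lowest 2.5% of random lists in both assays (ribosomal proteins, mitochondrial ribosomal proteins, translation factors). In the highest 2.5% lay 4 (unfolded protein response, Msn2 and Msn4, glycolysis, ergosterol). Random lists were not matched on coding length, with which the msp1 RPF ratio correlated (Spearman 0.312). Ribosomal protein genes were short, with a median of 432 nt against 1350 nt for other genes, so their RPF median is not free of that trend.

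In the pex19 deletion ADH4, ZRT1, ZAP1 and ZPS1, genes known to respond to zinc, were lower than in wild type. ADH4 (YGL256W; chromosome VII, 15159 to 16307) was lower by a log2 ratio of −3.46 in RNA-seq (−3.62 to −3.31) and −5.37 in RPF (−5.66 to −5.12), from 4558 to 118 RPF reads. Its annotated neighbour ZRT1, the high-affinity zinc transporter (YGL255W; chromosome VII, 20978 to 22108), was −1.67 and −1.72. ZAP1, the zinc-responsive transcriptional activator, was −1.75 and −1.03, and ZPS1 −1.92 and −3.55, the last from 3 RPF reads (−6.35 to −2.38). CYC7, the hypoxic isoform of cytochrome c, was −1.71 and −1.24, and ULI1 −2.50 and −2.18. With PEX19 these were the 7 genes at least 2-fold lower in both assays. PEX19, as the deleted gene, was bound to be shared, which leaves 6. By chance 0.12 would be shared if the assays were independent and every gene equally likely to pass. YLR307C-A was the only gene at least 2-fold higher in both (1.05 and 1.3), joined by MF(ALPHA)1 after removal of the length and GC trend. ICL1, isocitrate lyase of the glyoxylate cycle, stood just under that limit in RPF (1.02 and 0.999) and passed it under TMM over all listed genes. CIT2, the peroxisomal citrate synthase, was 0.90 and 0.92.

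Genes of amino acid synthesis controlled by Gcn4 were higher in the pex19 deletion, 36 of 42 in RNA-seq (median 0.21) and 39 in RPF (0.17), with HOM3 at 0.69 and 0.72 and ARG4 at 0.68 and 0.67. All 6 measured a-specific mating genes were higher in both assays (medians 0.49 and 0.97); the mating pheromone genes MFA1 and MFA2 were 0.66 and 1.04, and 0.76 and 0.98. MF(ALPHA)1, the measured gene of the α-specific list, was 1.12 and 0.89, and 11 haploid-specific genes had medians of 0.26 and 0.20, with AGA1 at 0.59 and 2.45. The Gcn4 and a-specific lists were the only 2 of 35 in the highest 2.5% of random lists in both assays, and 0 lay in the lowest 2.5% in both. Ribosomal protein genes had medians of 0.11 in RNA-seq and −0.11 in RPF. Unfolded protein response genes had medians of −0.20 (percentile 0.84) and −0.14 (3.16), with ERO1 at −0.48 and −0.30. SPS100, the only sporulation gene past the count minimum, was −0.80 and −1.58.

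In the double deletion few genes stood apart from wild type in both assays. BIO4, dethiobiotin synthetase, was −1.34 in RNA-seq (−1.58 to −1.11) and −1.50 in RPF (−1.78 to −1.23), and BIO2, biotin synthase, −1.10 and −1.20. FET3, the multicopper ferroxidase of iron uptake, was −1.09 and −1.20, NCA3 −1.01 and −1.21, and the biotin transporter gene VHT1 −0.88 and −0.88. The 15 measured genes of the iron regulon, FET3 and VHT1 among them, had medians of −0.03 and −0.10. MSP1 and PEX19 completed the 6 genes at least 2-fold lower in both assays. ERV1 stood just short of the limit in RNA-seq. It joined them with library totals, a pseudocount of 0.1, ribosomal protein genes left out or TMM over all listed genes. NCA3 stood at the limit in RNA-seq and dropped out with a pseudocount of 5 and after removal of the length and GC trend (−0.992 and −0.988). IMD2 was the only one higher (1.482 and 1.01), at the 2-fold limit in RPF; it dropped out with a pseudocount of 5 and under TMM over all listed genes, where the counts were 0 higher and 8 lower. ADH4 was −0.27 and −0.41. Without MSP1 and PEX19, bound to be shared as the deleted genes, 4 genes were lower. The numbers shared by chance would be 0.022 lower and 0.0064 higher, if the assays were independent and every gene equally likely to pass.

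**Figure D1:**
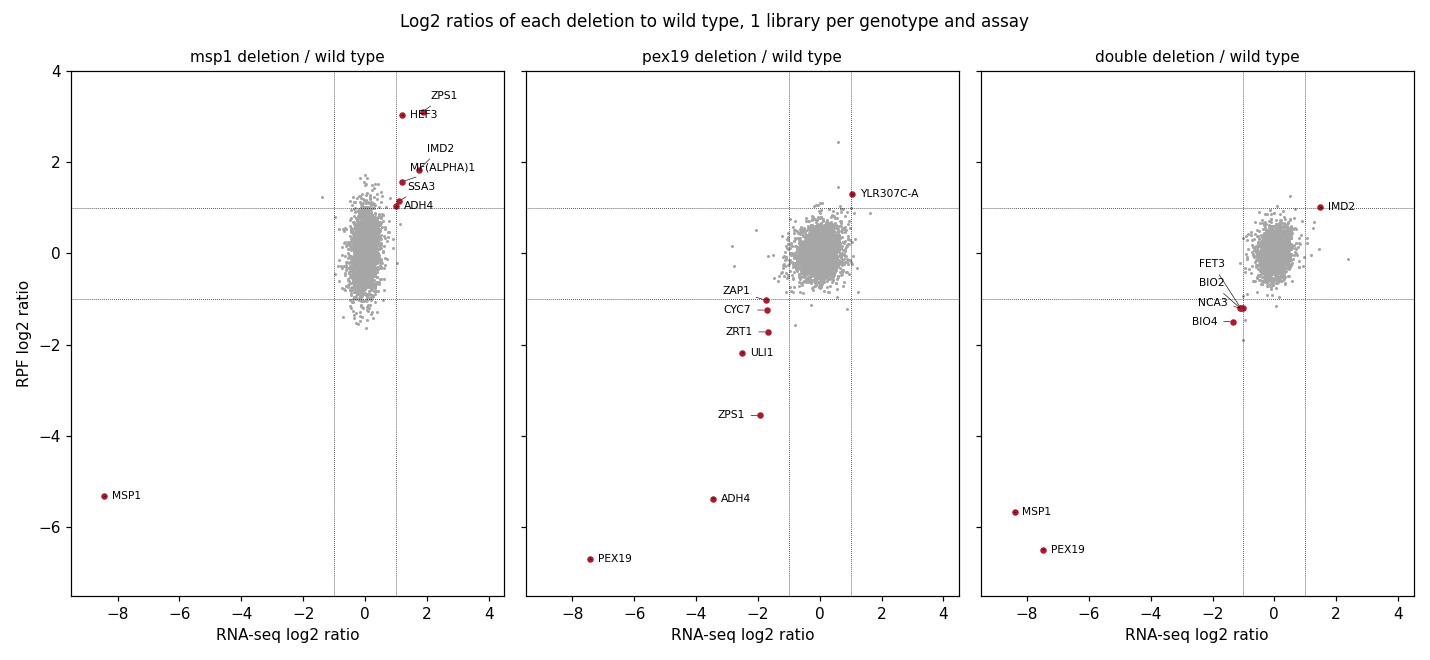
Log2 ratio to wild type in RNA-seq (horizontal) and RPF (vertical) of the 3737 genes past the count minimum, for the msp1, pex19 and double deletions; red points are genes at least 2-fold higher or lower in both assays and dotted lines mark 2-fold. MSP1 and PEX19, listed at 1 read where deleted, lie where the pseudocount puts them, and ADH4 stands at −3.46 and −5.37 in the pex19 deletion.

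Peroxisomal enzyme genes were slightly higher in the double deletion. Peroxisomal β-oxidation and matrix enzyme genes had medians of 0.17 in RNA-seq, with 15 of 17 higher, and 0.15 in RPF, with 12 higher; CTA1, peroxisomal catalase, was 0.89 and 0.70 and FOX2 0.62 and 0.78. Glyoxylate and gluconeogenesis genes had medians of 0.12 in both assays, and unfolded protein response genes 0.21 and 0.27, with the co-chaperone SIL1 at 0.48 and 0.41. In the single deletions the β-oxidation and matrix enzyme list had medians of the same sign (0.10 and 0.24 in msp1, 0.17 and 0.10 in pex19), as did the glyoxylate list (0.11 and 0.08 in msp1, 0.13 and 0.23 in pex19). Every deletion was set against the same wild-type libraries, so a low wild-type value alone would give such a shared sign. It is no independent agreement between the deletions. Under TMM over all listed genes the msp1 RPF median of the glyoxylate list turned to −0.122 and that of the enzyme list lay nearer 0. Ribosome biogenesis genes had medians of −0.16 in both assays of the double deletion, ribosomal protein genes −0.20 and −0.08, and Msn2 and Msn4 targets −0.11 and −0.13. In the double deletion the first 3 of these lists were the ones in the highest 2.5% of random lists in both assays, and the last 3 those in the lowest 2.5%. The 43 nuclear genes of the respiratory chain and ATP synthase had medians of −0.02 (percentile 44.99 of random lists) and 0.06 (percentile 100, 28 higher). The 74 mitochondrial ribosomal protein genes had medians of −0.03 (percentile 23.09) and 0.10 (percentile 99.87, 52 higher). Mitochondrial protein import genes had medians of 0.08 and 0.08, and mitochondrial chaperones and proteases 0.03 and 0.06. TMM over all listed genes turned the RPF medians of the respiratory chain and of the mitochondrial chaperones to −0.00508 and −0.0123, and brought that of the mitochondrial ribosomal proteins nearer 0. Of 26 Hsf1 targets 13 were higher in RNA-seq and 12 in RPF, and proteasome genes had medians of 0.03 and 0.02, the latter −0.05 under that scaling.

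Genes for peroxisomal membrane proteins, the clients of PEX19, were sparsely read, with 9 of 24 past the count minimum. Their medians in RNA-seq and RPF were −0.12 and 0.26 in the msp1, 0.05 and −0.01 in the pex19 and 0.10 and 0.08 in the double deletion. PEX3 was −0.76 and 0.16 in the pex19 deletion and PEX11 0.50 and −0.05. The pex19 RNA-seq library had 45 genes at least 2-fold lower than wild type, against 10 in RPF. The low PEX3 value in RNA-seq alone thus cannot be told apart from variation of that library. The 6 genes for tail-anchored proteins of the outer mitochondrial membrane had medians of 0.09 and −0.44 in the msp1 deletion, with GEM1 at 0.21 and −0.94. The bootstrap interval of that RPF median was wide (−0.884 to −0.0539). Across genes the msp1 RPF ratio rose with coding length (Spearman 0.312), which the median does not take into account. In the pex19 deletion the medians of these 6 genes were −0.22 and −0.03. In the double deletion they were −0.07 and 0.02, where the last was −0.05 under TMM over all listed genes. The 7 measured genes of mitochondrial import stress and pleiotropic drug resistance had medians of 0.13 and 0.01, −0.07 and 0.07, and 0.17 and 0.12 in the msp1, pex19 and double deletions, the msp1 RPF value changing sign with the scaling. No list of at least 3 genes fixed beforehand had a median beyond 2-fold in any deletion and assay, the most distant being the a-specific RPF median of 0.97.

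**Figure D2:**
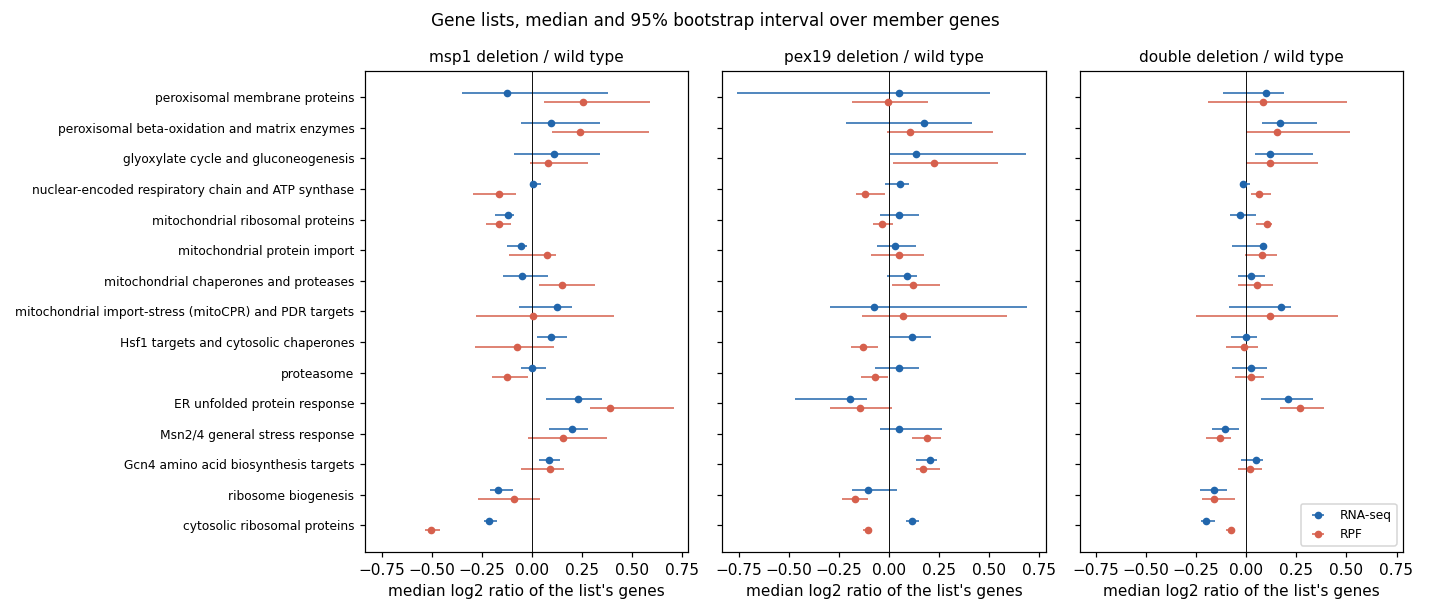
Median log2 ratio to wild type of the genes of 15 lists, in RNA-seq (blue) and RPF (red), for each deletion; bars are 95% bootstrap intervals over the genes of a list and say nothing of variation between cultures. Cytosolic ribosomal protein genes in the msp1 deletion stand lowest, at −0.21 and −0.50.

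Comparison of the double deletion with each single deletion gave the effect of a gene in a second background, from other libraries. Against the pex19 deletion, ADH4 was 3.19 higher in RNA-seq and 4.96 in RPF, ULI1 2.92 and 2.78, ZRT1 1.53 and 1.53, and ZPS1 1.34 and 3.58. There were 7 genes higher and 5 lower in both assays, the latter MSP1, ERV1 (−1.41 and −1.42), NCA3, TKL2 and MFA1. TKL2 dropped out after removal of the length and GC trend (RPF −0.994). Against the msp1 deletion 0 were at least 2-fold higher and 9 lower (1 and 8 with scaling by library totals), among them ZPS1 (−2.44 and −3.06), HEF3, SPS100 and GRE1; TMM over all listed genes moved the RPF median of all genes from 0.00282 to 0.134 here. ADH4, IMD2 and ZPS1 were at least 2-fold higher on loss of MSP1 both with and without PEX19. ADH4 and ZPS1, with PEX19 itself, were at least 2-fold lower on loss of PEX19 with and without MSP1. For ADH4 and ZPS1 both statements come from the same 4 libraries of each assay, highest in msp1 and lowest in pex19. They are thus no replicate of each other, and ADH4 in msp1 missed 2-fold with library totals (RNA-seq 0.99). For 17 genes the nonadditive value was past 2-fold in both assays, 8 higher and 9 lower. By chance 2.0 and 2.4 would be shared if the assays were independent and every gene equally likely to pass, which does not allow for the wider noise of low genes. ADH4 (2.17 and 3.93) and ULI1 (2.10 and 1.56) were among the highest and MF(ALPHA)1 (−2.04 and −2.94) and TKL2 (−1.47 and −1.78) among the lowest. This value carries the counting error of 4 libraries, and TMM over all listed genes gave 10 higher and 7 lower. A mean of at least 200 counts gave 1 higher and 6 lower, and a mean of at least 10 counts 37 and 18.

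**Figure D3:**
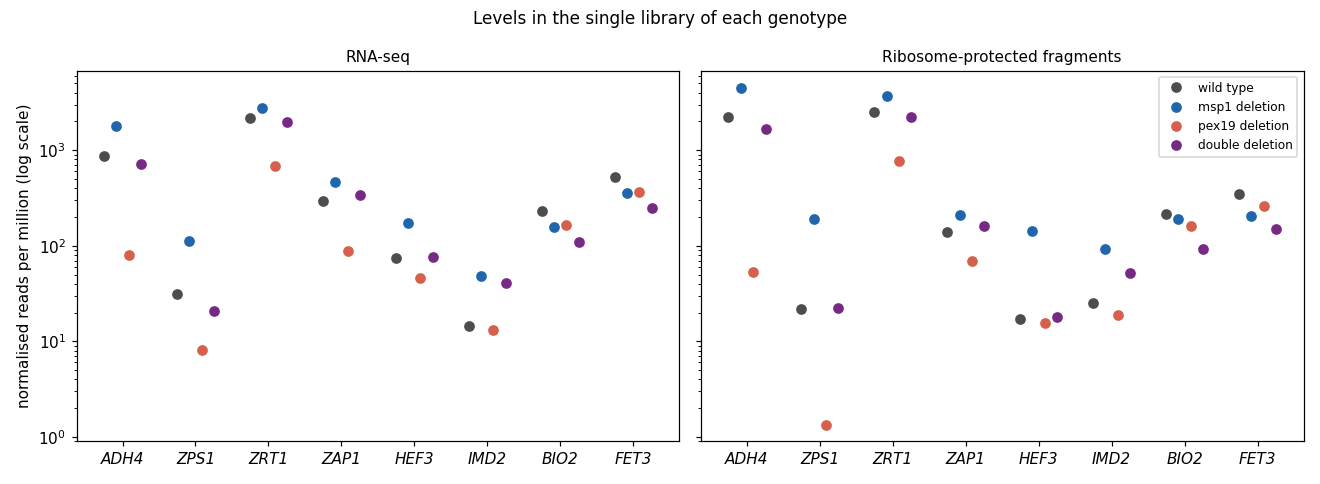
Normalised counts (CPM, log axis) of 8 genes in the RNA-seq (left) and RPF (right) library of each genotype; each point is 1 library. ADH4, ZPS1, ZRT1 and ZAP1 are lowest in the pex19 deletion and highest in the msp1 deletion, in both assays.

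The msp1 deletion had the most genes past 2-fold in translational efficiency. Its RPF library, the one with the lowest total, also had the widest spread of ratios to wild type. The scaled median absolute deviation of the RPF log2 ratio was 0.43, against 0.274 in pex19 and 0.223 in the double deletion. In RNA-seq it was 0.188 in msp1, so the count cannot be assigned to the genotype rather than that library. JID1, a mitochondrial J-domain protein gene, was 2.65 higher there and HEF3 1.82 higher. JID1 was −1.40 in RNA-seq and 1.24 in RPF, while PRP11 and SLX8 were lowest (−1.68 each), with 15 RPF reads apiece. In the pex19 deletion PFD1, a prefoldin subunit, was 2.98 higher, CMC4 2.57 and LSO2 2.49. Each came from 13 to 20 RNA-seq reads against 102 to 115 in wild type (PFD1 −2.82 in RNA-seq, 0.16 in RPF). The pex19 RNA-seq library stood apart from the other RNA-seq libraries, with 783 genes listed at 1 read against 511 to 528. YFR032C-B (−2.10) and IES5 (−2.07) were lowest. In the double deletion BUD23, an 18S rRNA methyltransferase gene, was −2.51, from an RNA-seq ratio of 2.39 with an RPF ratio of −0.12. Leaving out the deleted genes, 145 genes lay past 2-fold in the msp1 deletion (83 higher, 62 lower), 99 in the pex19 deletion (57 and 42) and 28 in the double deletion (17 and 11); with the deleted genes the counts were 146, 99 and 30. The split depends on the count minimum, on the scaling and on the length and GC trend. A mean of at least 200 counts gave 8 higher and 7 lower for msp1. It gave 3 and 4 for pex19 and 0 and 2 for the double deletion. TMM over all listed genes gave 35 higher and 115 lower for msp1 and 14 and 14 for the double deletion, and library totals gave 103 and 49 for msp1. Removal of the trend gave 79 and 37 for msp1 and 64 and 27 for pex19. Without replicates these ratios of genotype and assay have no test.

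Ribosomal protein genes had a lower translational efficiency in both single deletions, with medians of −0.30 in msp1 (127 of 137 below 0) and −0.24 in pex19 (110 of 137), against 0.11 in the double deletion. With a length and GC trend fitted on the other genes removed, the single-deletion medians were −0.0395 (−0.0797 to 0.0215 by bootstrap) and −0.125 (−0.17 to −0.0573). The value of the double deletion is given without that removal. Its translational efficiency ratio fell with coding length (Spearman −0.149), so the contrast with the single deletions is not free of the trend. Respiratory chain genes had medians of −0.24, −0.13 and 0.09; the first and last became 0.00238 and −0.00527 after removal of the length and GC trend. Across genes, coding length correlated with the RPF ratio with a Spearman coefficient of 0.312 in msp1, 0.207 in pex19 and −0.0694 in the double deletion; genes are not independent replicates.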

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

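The zinc gene lists, the zinc test in the msp1 deletion and the test on cultures per genotype were chosen only after results or counts were seen. So were TMM over all listed genes, the removal of a length and GC trend and the use of intervals in the tests on ribosomal protein genes. For 3 named genes the ratios for a deletion had opposite signs, in both assays, between the strains with and without the other gene, with ratios past 2-fold in one background. These differences were not tested, since each value rests on 1 library. For MF(ALPHA)1 loss of MSP1 gave 1.21 and 1.57 against wild type and −0.83 and −1.37 against the pex19 deletion, a mean nonadditive value of −2.49. For TKL2 loss of MSP1 gave −1.12 and −1.09 against the pex19 deletion and 0.36 and 0.69 against wild type (−1.625); removal of the length and GC trend brought the RPF ratio against pex19 to −0.994, short of 2-fold. For YLR307C-A loss of PEX19 gave 1.05 and 1.3 against wild type and −0.13 and −0.09 against the msp1 deletion (−1.284). The latter ratios lay within counting error of 0 (intervals −0.384 to 0.121 and −0.452 to 0.283), and TMM over all listed genes turned the RPF ratio to 0.05, so an opposite direction was not shown for YLR307C-A.

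ADH4, ZPS1, ZRT1, ZAP1 and HEF3, known to respond to zinc and picked for these values, had medians of 1.02 and 1.03 in the msp1 deletion and −1.75 and −1.72 in the pex19 deletion. Of 14 further targets of the zinc activator Zap1, 10 were measured. In msp1 their medians were 0.34 in RNA-seq and 0.74 in RPF, both at percentile 100 of matched random lists. This test was written after its values were seen. Noise independent between genes would rarely give such medians, but the outcome was known when the test was written, so no conclusion is drawn from it. The random lists were also not matched on coding length, with which the msp1 RPF ratio rose (Spearman 0.312). Random lists of unrelated genes cannot model a shift shared by these targets in 1 library or culture, so a shift of that kind stays open too. In pex19 the zinc test was set before its own values were seen, but after the zinc genes named above had been noticed. It did not go beyond noise: the median was −0.28 in RNA-seq (percentile 0.35) but −0.01 in RPF (43.88). Noise may thus account for the wider group in that strain. ADH1 and ADH3, repressed by Zap1 and too few to decide, were however higher (medians 0.475 and 0.294, percentiles 99.09 and 95.93). Whether the genotype or the zinc supply of its culture lies behind the order of the strains cannot be told apart, since there was 1 culture per genotype.

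Many genes lay past 2-fold in translational efficiency, and counting error of independent reads does not account for them. Among 100 simulations of unchanged genes at the observed depths the highest counts were 5 in msp1, 3 in pex19 and 3 in the double deletion, against 146, 99 and 30 observed. Removing the length and GC trend left 117 in msp1 and 91 in pex19, which argues against that trend as the whole cause. Variation between libraries, such as fragment loss or amplification, stays open beside the genotype, as no replicate library was used here.

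Ribosomal protein genes were lower in translational efficiency in both single deletions, each set against the same wild-type libraries. With the length and GC trend fitted on the other genes removed, their median moved from −0.303 to −0.0395 in msp1 (−0.0797 to 0.0215 by bootstrap) and from −0.24 to −0.125 in pex19 (−0.17 to −0.0573). Both stayed in the lowest 2.5% of random lists (percentiles 1.43 and 0.0), but little of the size was left in msp1, and in pex19 the median just met the bound set beforehand for excluding the trend while its interval, added to the test afterwards, crossed it. The trend and an effect of genotype thus cannot be told apart, and the fit at these lengths rests on few genes: 249 of 3598 others were no longer than the median ribosomal protein gene (432 nt). Reads shared between gene pairs are less likely in pex19, where the 19 ribosomal protein genes without an A or B copy had a median of −0.282 (−0.322 to −0.183); in msp1 it was −0.25 (−0.316 to −0.129), where the median met its bound and the interval did not.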

How the results depend on the processing

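TMM over all listed genes and the removal of a length and GC trend were chosen only after the counts were seen. Of 172 counts of genes recomputed under other settings, 109 stayed within 1.5 times the reported one and 63 did not. Of 3123 list medians 3010 stayed within their bootstrap interval, 106 moved outside it and 7, of lists that stood apart from random ones, changed sign. Over all 315 medians 77 changed sign with a scaling, none above 0.195 in size. The 518 values of named genes covered only genes past 2-fold in both assays of the comparison concerned. Of them 510 stayed within their counting interval, 8 moved and 0 changed sign. Ratios of that size left little room for a change of sign, and ratios of named genes nearer 0 were not covered. Depth limits low genes, above all in the RPF of the msp1 deletion. Leaving out a replicate and scaling by spike oligonucleotides were not run.

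Counts below give genes past 2-fold in both assays unless stated. A mean of at least 200 counts, which tests fewer genes, gave 2 higher and 0 lower in msp1, 3 lower in pex19 and 0 higher in the double deletion, 4 lower in the double against msp1, and 3 higher and 2 lower against pex19. It gave 15, 7 and 2 genes by translational efficiency in msp1, pex19 and the double deletion and 7 nonadditive genes. A mean of at least 10 counts, which adds low genes, gave 2 higher in pex19, 2 in the double deletion and 12 in the double against pex19, with 428, 348 and 173 by translational efficiency and 55 nonadditive genes. No count minimum gave 37 higher and 4 lower in msp1, 11 and 27 in pex19, 16 and 10 in the double deletion, 7 and 23 in the double against msp1, and 47 and 12 against pex19. It gave 756, 709 and 462 by translational efficiency and 112 nonadditive genes.

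The RNA-seq library alone, which asks for 1 assay instead of both, gave 2 lower in msp1, 11 higher and 45 lower in pex19, 8 higher in the double deletion, 8 higher in the double against msp1, 47 higher and 26 lower against pex19, and 102 nonadditive genes. The RPF library alone gave 68 higher and 47 lower in msp1, 9 higher in pex19, 3 higher in the double deletion, 45 higher and 58 lower in the double against msp1, 12 lower against pex19, and 326 nonadditive genes. A 1.5-fold threshold, which is looser, gave 13 higher and 7 lower in msp1, 18 and 18 in pex19, 5 and 13 in the double deletion, 10 and 25 in the double against msp1, and 25 and 27 against pex19. Library totals gave 1 higher in the double against msp1. A pseudocount of 5 gave 0 higher in the double deletion. TMM over all listed genes gave 2 higher in pex19 and 0 in the double deletion, and removal of the length and GC trend gave 2 higher in pex19; the cause was not tested.

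Removing the length and GC trend turned the translational efficiency medians of respiratory chain genes to 0.00238 in msp1 and −0.00527 in the double deletion, and the RPF median of mitochondrial ribosomal protein genes in msp1 to 0.00424. TMM over all listed genes turned the msp1 RPF medians of Msn2 and Msn4 targets to −0.0418 and of glycolytic genes to −0.076. A mean of at least 200 counts turned the translational efficiency median of ergosterol genes in msp1 to −0.0374 and of methionine genes in the double deletion to 0.00299. For these 7 medians the cause was not tested.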

Other observations

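The gene lists and the neighbouring genes were fixed beforehand, and only the choice of lists described here and the ranking of the neighbours were made after values were seen. In the msp1 deletion histone genes had medians of −0.09 in RNA-seq and −0.39 in RPF, with 10 of 10 below wild type in RPF. Several have near-identical copies. Across genes the msp1 RPF ratio also rose with coding length (Spearman 0.312), which these histone medians do not take into account. The 3 measured hexose transporter genes had medians of 0.20 and 0.83. In the pex19 deletion targets of the stress activators Msn2 and Msn4 had medians of 0.05 and 0.19, with 23 of 26 higher in RPF, and Hsf1 targets 0.11 and −0.13, with 20 of 26 lower in RPF.

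ERV1 and UBC9, each beside a deleted gene, stood apart in both strains that carry the deletion concerned. Loss of MSP1 gave 4 log2 ratios per gene (both assays, with and without PEX19). Ranked by the least extreme of the 4, ERV1 was at place 1 of 3735 genes among those lower, with −0.71 as its ratio nearest 0. In the same ranking for loss of PEX19, UBC9 was at place 1 of 3735 among those higher, with 0.77 as its ratio nearest 0. IDP1 and COX9, at places 224 and 984 of that ranking, were not higher in all 4 ratios, the least of which were −0.001 and −0.153.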
